A study of Mus musculus with 32 samples.

How the data were processed

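The values analysed are raw counts per gene for 32 libraries, as the authors deposited them. The authors' notes name FastQC 0.10.1 for read quality and HTSeq 0.10.0 for counting against mm10/GRCm38. The aligner, the strand setting, the counting mode and the annotation release are not given in the sources used here. Libraries were made from poly(A) RNA with the NEBNext Ultra II kit after extraction with the Qiagen RNeasy Micro kit. The table holds 55414 Ensembl gene IDs, of which 52081 (99.75% of the counts) matched a symbol in the GENCODE M21 annotation of GRCm38. Symbols and coordinates come from that annotation, whose release may differ from the one used for counting. Each column belonged to 1 sample and 0 columns were without one. The lowest chi-square over its degrees of freedom between any 2 of the 32 libraries was 9.8 over all 496 pairs (9.88 over the 48 within a group), far above the 1 that a resequenced library would give, so no library was a copy or a resequencing of another.

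Differences were tested in edgeR 4.0.16 (R 4.3.3) with TMM factors, the default filter on low counts by group and quasi-likelihood fits with robust dispersion. All libraries stood in 1 model with 1 mean per group, and 16760 genes were tested. Tests were two-sided, and p was adjusted by Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05. The 14 contrasts were iCre against LacZ in each of 4 conditions, their average, each stimulus against SS in each vector, and the 3 interactions. Gene lists were tested with camera from limma 3.58.1, with the preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a contrast. DESeq2 1.42.0 was the other tool. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

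The contrasts, the test, the gene lists and the rule for named genes were fixed before the data were examined. Genes named are Pkm and Map3k7 everywhere. For iCre against LacZ within a condition they are up to 8 genes that rose and 8 that fell, by size of change, and for a stimulus up to 6 and 6. These need an adjusted p under 0.05, an average log2 CPM of at least 1 and groups that do not overlap. For the average and the interactions up to 6 rose and 6 fell under the same limits without the last. Predicted genes, pseudogenes and unnamed IDs were counted and not named. For each list described, up to 4 members with the smallest p were eligible, along with any marker of another cell type. Some eligible genes are left out for length, and the label markers and the genes of single replicate numbers were chosen after their values were seen.

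The 26 lists hold 452 members, of which 450 are in the table. They cover glycolysis, pentose phosphate, serine and one-carbon synthesis, the TCA cycle with pyruvate entry, oxidative phosphorylation, HIF targets, extracellular matrix, contractile genes, TGFb targets, ERK feedback, NFkB targets and cytokines, matrix proteases, interferon-stimulated genes, cell cycle, p53 targets, ATF4 and unfolded protein response, NRF2 targets, cholesterol synthesis, fibroblast identity and the mitochondrial genome. Markers of cardiomyocytes, endothelial cells, leukocytes, mural cells, Schwann cells and mesothelial cells cover other cells a cardiac culture can hold. The Schwann list had 2 tested genes, under the 3 that a test needed, and the cardiomyocyte list had 3.

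Replicate numbers 1 to 4 stand in every title. Deviations from the group mean correlated between same-numbered libraries of compared groups at 0.153 to 0.857 over 40 pairs, each above the 0.1 fixed beforehand, so the numbers pair the libraries. The first component of those deviations held 51.3% of their variance. The fit with the number as a block was planned as an alternative and is printed beside many of the results that it changes, though not all. Added after the data were seen were a block for each pair of condition and number (for iCre against LacZ), fits without the 8 number 4 libraries, with and without the block, and counts summed over the 4 conditions. The pair block treats 16 pairs as independent, although they share 4 numbers. Averages from the main fit and the replicate block likewise hold no term for a vector difference that repeats within a number.

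A self-test changed genes by known folds in simulated counts with the spread of these libraries. Only genes with a mean of at least 1 CPM were changed. Runs without a block held no number effects, so their rates are those of unpaired libraries. Number effects, where simulated, were the same in all conditions and in both vectors. No number was given a vector difference of its own. The rates for the average therefore do not cover differences that repeat over the conditions of a number. At 1.5, 2 and 4-fold the model found 32.8%, 62.7% and 90.9% of changed genes for iCre against LacZ in SS, with 7 calls on unchanged genes among 131. For the average over conditions it found 70.1%, 88.1% and 98.5% (7 among 178), for TGFb in LacZ 34.3%, 68.7% and 83.3%, and for the bFGF interaction 22.4%, 49.3% and 83.3%. With simulated number effects the block found 83.6%, 100% and 100% for the average (9 among 198) and the pair block 91%, 97% and 100% (8 among 200). With genes drawn independently, the cholesterol synthesis list raised 1.5-fold passed with the preset (adjusted p = 1.23e-28) and with the estimated correlation (adjusted p = 1.47e-10). There 0 other lists passed with the preset.

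Alternatives were DESeq2's size factors in edgeR, total counts as the only scaling, no filter on low counts, a filter of 1 CPM in 4 libraries, DESeq2, the replicate block, a fit to the libraries of the contrast alone, LacZ libraries grouped by their treatment tags, and each library left out in turn. A change of sign counts as a reversal only where a fit calls the gene. Splits of 8 libraries into 4 and 4 number 35 and were all fitted, and 50 were drawn for the average and for each interaction. Where a group had 0 counts for a gene, a bound was taken against 3 counts over the group, and 1 to 3 counts gave a ratio with a 95% counting interval. PKM1 and PKM2 were not separated, since the table counts genes.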

Results

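Poly(A) RNA was sequenced from cultured mouse cardiac fibroblasts that carry a floxed Pkm allele (given as Pkm2fl/fl on C57BL/6J). Pkm encodes pyruvate kinase, the enzyme of the last step of glycolysis, and the series title names a switch of its product from the PKM2 to the PKM1 form. Cells were transduced with the recombinase iCre or with LacZ as the control. They were then left without a stimulus (SS, an abbreviation that the labels do not spell out) or treated for 24 h with basic fibroblast growth factor (bFGF, 20 ng/ml), interleukin-1 beta (IL-1b, 15 ng/ml) or transforming growth factor beta (TGFb, 10 ng/ml). The doses come from a protocol text that otherwise speaks of TAK1fl/fl mice and of a TNFa arm. These 2 vectors and 4 conditions make 8 groups of 4 libraries, 32 in all. Total counts ran from 20736203 to 34995038 per library, with group means from 23219664 (LacZ, SS) to 31073383 (iCre, IL-1b). The iCre library was the deeper in 16 of 16 pairs of the same condition and replicate number (mean ratio 1.17, range 1.02 to 1.22).

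Groups were taken from the sample titles, because the treatment tags of the 16 LacZ libraries contradict them. The tags of the 4 LacZ bFGF libraries name iCre as well as another stimulus, so there the vector is in conflict too. Genes chosen after the values were seen fitted the titles for the stimulus, and none of them tests the vector, which rests on the titles. Nos2, the inducible nitric oxide synthase, stood at 257 ± 55.9 CPM (counts scaled to a common library total; mean ± SD, n = 4) in LacZ libraries titled IL-1b and at 276 ± 50.9 in iCre libraries titled IL-1b. Its means were 0.371 to 0.518 CPM in the other 6 groups. Spry4, a feedback inhibitor of growth factor signaling, stood at 14.7 ± 9.61 CPM in LacZ SS, 117 ± 18.6 in LacZ bFGF and 93.6 ± 9.18 in iCre bFGF. Pmepa1, a TGFb-induced inhibitor of Smad signaling, stood at 225 ± 44.7 CPM in LacZ SS, 1300 ± 143 in LacZ TGFb and 1090 ± 134 in iCre TGFb.

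Libraries that share a replicate number resembled each other across groups. Once group means were removed, 31 of 32 libraries had their highest mean correlation with the libraries of their own number in the other groups. Number 4 stood farthest apart. In its 8 libraries 12 leukocyte marker genes had a median log2 level of -2.47 relative to the other numbers, against 1.01 for number 1, -0.91 for number 2 and 2.36 for number 3. The labels do not say whether a number marks a mouse, an isolation or a day. The p-values below therefore measure the spread between samples of unstated origin. A fit with the replicate number as a block is given beside many of the results that it changes, though not all. Values of ± after a log2 fold change are standard errors, with n = 4 libraries per group (16 per vector for averages). Those 16 share 4 replicate numbers, and neither the main fit nor the replicate block allows for a vector difference that repeats within a number. Leukocyte markers had iCre minus LacZ medians of -0.774, -0.721, -0.507 and -0.575 (SS, bFGF, IL-1b, TGFb) in number 2. In number 3 these were 0.407, 0.29, 0.58 and 0.658. For such genes the errors of an average can be too small, which counts summed over the conditions avoid.

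The comparison of iCre with LacZ asks what recombination at Pkm changes. Pkm itself (ENSMUSG00000032294, chromosome 9, 59656368 to 59679375, GRCm38) was lower in the iCre library of 16 of 16 pairs. In SS it stood at 785.9 ± 247 CPM (SD, n = 4) with LacZ and 533.4 ± 177 with iCre. With bFGF it stood at 1075 ± 60.6 and 779.7 ± 147, with IL-1b at 1993 ± 488 and 1392 ± 349, and with TGFb at 1538 ± 160 and 1107 ± 181. The differences were -0.56, -0.46, -0.52 and -0.47 on the log2 scale (each ± 0.23, adjusted p = 1 in each). With a block for each pair of condition and number, added after the data were seen, Pkm fell in SS (adjusted p = 0.0176), with bFGF (adjusted p = 0.0284) and with TGFb (adjusted p = 0.0158), and with IL-1b the adjusted p was 0.0622 (each ± 0.08). Averaged over the 4 conditions Pkm was -0.50 ± 0.11, a fold of 0.705. That average missed the threshold in edgeR (adjusted p = 0.0744) and passed it with the replicate block (-0.51 ± 0.09, adjusted p = 0.00381) and in DESeq2 (adjusted p = 0.00625). With counts summed over the conditions per number, in the same blocked design, it missed the threshold (-0.49 ± 0.05, adjusted p = 0.0572). Without iCre SS replicate 3 the adjusted p was 0.0327, and without LacZ IL-1b replicate 4 it was 0.0305. The exact two-sided sign-flip test over the means of the 4 numbers gave p = 0.125, the smallest that 4 numbers allow.

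Both IL-1b and TGFb raised Pkm with either vector. With IL-1b it rose 2.54-fold in LacZ (1.34 ± 0.23, adjusted p = 0.000122) and 2.61-fold in iCre (1.38, adjusted p = 0.000108). With TGFb it rose 1.96-fold in LacZ (0.97, adjusted p = 0.00103) and 2.08-fold in iCre (1.05, adjusted p = 0.000629). Its bFGF values of 0.45 and 0.55 did not pass (adjusted p = 0.318 and 0.211). The counts are per gene, so they cannot separate PKM1 from PKM2. Map3k7 (ENSMUSG00000028284, chromosome 4, 31964097 to 32023467), which encodes the kinase TAK1, stood at 112 to 134 CPM in the 8 groups and did not pass for iCre against LacZ (averaged -0.08 ± 0.06, adjusted p = 0.855).

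**Figure D1:**
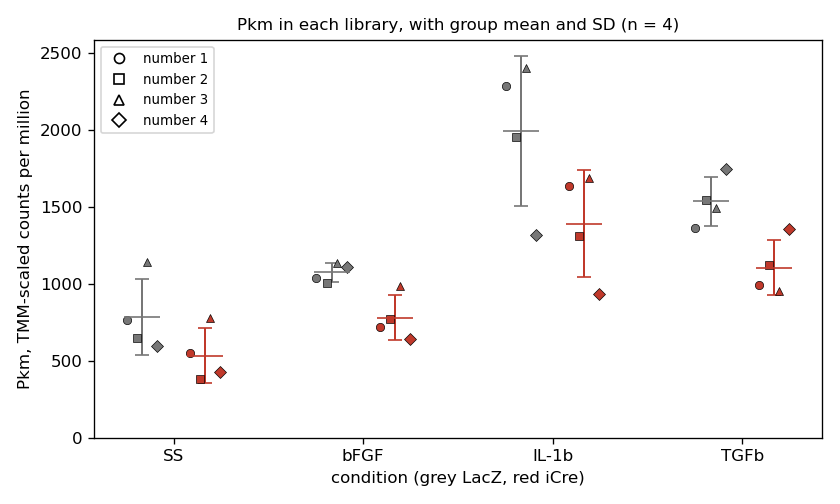
Pkm in TMM-scaled CPM in each of the 32 libraries, by condition (x axis) and vector (grey LacZ, red iCre), with a symbol for each replicate number and bars for the group mean ± SD (n = 4). In 16 of 16 pairs of the same condition and number the iCre library is the lower, and both vectors stand highest with IL-1b.

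Averaged over the 4 conditions, 18 genes changed between iCre and LacZ in edgeR, of which 3 rose and 15 fell. Comp, a cartilage matrix protein, fell to 0.485-fold (-1.04 ± 0.17, adjusted p = 0.0064), and Trf, the iron carrier transferrin, fell to 0.495-fold (-1.01 ± 0.12, adjusted p = 0.000208). Lrrn2 fell to 0.544-fold (-0.88 ± 0.16), Prrg3 to 0.56-fold (-0.84 ± 0.17), the aldehyde dehydrogenase Aldh3a1 to 0.569-fold (-0.81 ± 0.16) and Aass, an enzyme of lysine breakdown, to 0.607-fold (-0.72 ± 0.13). Sncg, which encodes gamma-synuclein, rose 1.58-fold (0.66 ± 0.13, adjusted p = 0.0298). With the replicate block 475 genes changed (186 rose, 289 fell). In that fit the urea transporter gene Slc14a1 rose (1.65, adjusted p = 0.000126), as did the angiotensin receptor gene Agtr2 (1.5, adjusted p = 0.00646) and Dlk1 (1.37, adjusted p = 0.00639), while the transcription factor gene Sox6 fell (-1.04, adjusted p = 0.000519). With counts summed over the conditions, in the same blocked design, Slc14a1 passed (0.99, adjusted p = 0.0223), and Agtr2 (0.81, adjusted p = 0.0999), Dlk1 (1.05, adjusted p = 0.578) and Sox6 (-0.99, adjusted p = 0.283) did not. Slc14a1 and Agtr2 had most of their counts in number 4 (66.9 ± 76.9 and 104 ± 78.3 CPM, SD, n = 8, against means of 0.0447 to 1.16 CPM in the other numbers), and without it they did not pass in edgeR without the block (adjusted p = 0.554 and 0.711) or with it (adjusted p = 0.124 and 0.482), while Sox6 passed in both (adjusted p = 0.0107 and 0.00217). DESeq2 changed 85 genes (27 rose, 58 fell), and with total counts as the only scaling 5 rose and 13 fell.

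Without the 8 libraries of number 4 (a choice made after the data were seen) 114 genes changed, and Lrrn2 (adjusted p = 0.0621) and Prrg3 (adjusted p = 0.15) no longer passed. With counts summed over the conditions, so that each vector has 4 values, 9 genes changed (2 rose, 7 fell), and of the 7 named genes Comp alone passed (adjusted p = 0.0374). The count of 18 dropped to 7 without iCre SS replicate 1, iCre TGFb replicate 1, LacZ IL-1b replicate 1 or LacZ SS replicate 1. It was 8 without iCre IL-1b replicate 1, LacZ bFGF replicate 2 or LacZ IL-1b replicate 2, 9 without LacZ SS replicate 2, and 11 without iCre bFGF replicate 1 or iCre TGFb replicate 3. Sncg missed the threshold without any of 14 libraries (0.61 to 0.69, adjusted p = 0.0503 to 0.0656), namely those 10 and iCre IL-1b replicate 3, iCre SS replicate 3, LacZ SS replicate 4 and LacZ TGFb replicate 2. Prrg3 missed it without any of 17 (-0.85 to -0.78, adjusted p = 0.0515 to 0.0696), the same 14 less iCre SS replicate 3, together with number 4 of the 4 iCre groups. Aldh3a1 missed it without any of 9 (-0.82 to -0.76, adjusted p = 0.0507 to 0.0622), namely iCre replicate 1 in IL-1b, SS and TGFb, LacZ replicate 1 in IL-1b and SS, and LacZ replicate 2 in bFGF, IL-1b, SS and TGFb.

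Among the gene lists fixed before the data were examined, glycolysis and cholesterol synthesis had the lowest p between the vectors with the preset correlation. Of 21 tested glycolysis genes (Pkm is not on the list) 19 were higher in iCre, with a median log2 fold change of 0.18. None passed over all 16760 genes in edgeR and 1 passed adjusted over the list alone, the glucose transporter gene Slc2a1 (0.30 ± 0.07, adjusted p over all genes 0.0587). It passed with the block (adjusted p = 0.00918). The list test (limma camera) gave an adjusted p of 2.58e-06 with its preset correlation, and adjusted p = 0.253 with an estimated correlation. Without number 4 the glycolysis list passed with both (adjusted p = 1.13e-15, and adjusted p = 0.0375 with an estimated correlation). That choice, made after the data were seen, left out the number with the smallest glycolysis difference within pairs. Its list medians were 0.015, -0.047, 0.066 and 0.044 in SS, bFGF, IL-1b and TGFb. Means of the 4 numbers ran from 0.02 to 0.28 (exact sign-flip p = 0.125 over the 4 numbers). All 20 cholesterol synthesis genes were lower in iCre (median -0.26), and 0 passed in edgeR over all genes or over the list alone, while 3 fell with the block. The list's adjusted p was 4.42e-05, and adjusted p = 0.636 with an estimated correlation. Stard4, a sterol carrier, stood at -0.48 ± 0.28 and the isomerase gene Idi1 at -0.58. In the fit with a block for each pair of condition and number, added after the data were seen, 18 of the 20 fell, among them Idi1 (-0.62, adjusted p = 0.000523) and Stard4 (-0.50 ± 0.08, adjusted p = 0.00107), and the list passed with an estimated correlation (adjusted p = 0.0314). That fit takes the 16 pairs as independent, although they share 4 numbers. With counts summed per number all 20 were lower (median -0.38) but 2 fell past the threshold, and Idi1 (-0.69 ± 0.08, adjusted p = 0.0638), Stard4 (-0.44 ± 0.07, adjusted p = 0.134) and Slc2a1 (0.27 ± 0.06, adjusted p = 0.218) missed it.

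A further 9 lists passed with the preset correlation and larger p, and none with an estimated one. Higher in iCre were matrix proteases and their inhibitors (14 of 19 higher, median 0.15, adjusted p = 0.0308, and adjusted p = 0.253 with an estimated correlation), HIF targets (10 of 14, 0.15, 0.0153, and adjusted p = 0.536 with an estimated correlation) and the TCA cycle with pyruvate entry (15 of 21, 0.04, 0.0459, and adjusted p = 0.394 with an estimated correlation). The protease gene Mmp12 stood at 1.12 ± 0.42 (adjusted p = 0.484). Lower in iCre were fibroblast identity genes (5 of 16 higher, median -0.19, adjusted p = 0.00835), TGFb targets (5 of 20, -0.13, 0.0114) and p53 targets (6 of 20, -0.06, 0.0153), each with adjusted p = 0.394 with an estimated correlation. Extracellular matrix (11 of 35, -0.11, 0.0153) and contractile genes (2 of 18, -0.13, 0.0308) had adjusted p = 0.636 with an estimated correlation, and cell cycle genes (5 of 31, -0.27, 0.00776) had adjusted p = 0.748 with an estimated correlation. No member of these 9 lists passed in edgeR over all genes, and with the block the fibroblast gene Dpt fell (-0.38, adjusted p = 0.000228), though not with summed counts (-0.38, adjusted p = 0.181). Without number 4 the calls of 7 of these lists ended: TCA cycle (0.14), matrix (0.121), contractile (0.341), TGFb targets (0.0646), cell cycle (0.0644), p53 targets (0.14) and fibroblast identity (0.121). With the block the TCA and contractile calls ended (0.0755 each).

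The other lists did not pass for iCre against LacZ: pentose phosphate (median -0.02), serine and one-carbon synthesis (0.02), oxidative phosphorylation (0.02), ERK feedback (0.04), NFkB targets and cytokines (0.05), interferon-stimulated genes (0.02), ATF4 and unfolded protein response (0), NRF2 targets (0.06) and the mitochondrial genome (0.04). With total counts as the only scaling the pentose phosphate median turned to 0.01. Within the NFkB list, adjusted over the list alone, the chemokine gene Ccl7 rose (0.42 ± 0.11, adjusted p over all genes 0.167) and the adhesion gene Icam1 fell (-0.49 ± 0.11, adjusted p over all genes 0.0788). With the block Icam1 also fell over all genes (adjusted p = 0.000228), as it did with summed counts (adjusted p = 0.0388). Markers of other cell types did not pass as lists: cardiomyocyte (0.23), endothelial (0.07), leukocyte (0.21, with 12 of 12 higher in the unpaired fit, adjusted p = 0.819, but lower in iCre in 10 of 16 pairs with a mean difference of -0.07), mural (0.02) and mesothelial (0.38). The Schwann list (-0.11) has 2 tested genes and was not tested with camera. Within pairs it was lower in iCre in 14 of 16 (mean difference -0.19, means of the 4 numbers -0.4 to -0.07, exact sign-flip p = 0.125 over the 4 numbers and 0.005 over the 16 pairs, which share numbers). With the block the mesothelial marker Msln rose (1.07, adjusted p = 0.0149), Upk3b fell (-0.76, adjusted p = 0.00586) and the endothelial receptor gene Tek fell (-0.51, adjusted p = 0.0286), and with summed counts none of these 3 passed (adjusted p = 0.392, 0.25 and 0.457). The cardiomyocyte marker Tnnt2 also fell with the block (-1.02, adjusted p = 0.0383), though not with summed counts (-1.03, adjusted p = 0.465).

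Within each condition, 0 genes changed between iCre and LacZ in edgeR or in DESeq2. At an unadjusted p under 0.05 edgeR gave 317 genes in SS, 335 with bFGF, 251 with IL-1b and 526 with TGFb, and DESeq2 gave 363, 381, 283 and 566. Each lies below a share of 0.05 of the 16760 genes tested, which chance alone would give on average. Both fits leave out the pairing by number, so their 0 calls do not show that nothing changed. The pair block gave 1324, 1456, 966 and 1820 genes at that unadjusted p. With the replicate block 1 gene fell with bFGF and 5 rose with TGFb, with 0 in SS and IL-1b. With the pair block 14 changed in SS, 15 with bFGF, 46 with TGFb and 0 with IL-1b. Glycolysis genes were higher in iCre in each condition: 18 of 21 in SS (median 0.16, camera adjusted p = 0.00191), 20 with bFGF (0.24, 0.000312), 19 with IL-1b (0.2, 0.00304) and 20 with TGFb (0.15, 0.0145). With an estimated correlation these had adjusted p = 0.621, 0.626, 0.815 and 0.714. All 20 cholesterol synthesis genes were lower in SS (median -0.38, 0.00112, and adjusted p = 0.622 with an estimated correlation) and with TGFb (-0.51, 4.33e-06, and adjusted p = 0.714 with an estimated correlation). With IL-1b 19 of the 20 were lower (-0.18, adjusted p = 0.0814, and 0.000112 with the block), and with bFGF 12 were (-0.1, adjusted p = 0.536). In the unblocked fit with IL-1b 0 lists passed with an estimated correlation. Interferon-stimulated genes were lower in iCre with IL-1b (2 of 25 higher, -0.19, 0.0193) and higher with TGFb (23 of 25, 0.3, 0.000352), and the first call ended with the block (0.0502) and without number 4 (0.302). With an estimated correlation they had adjusted p = 0.815 and 0.714. Within pairs the TGFb differences of the interferon list were -0.05, -0.45, 1.15 and 0.45 for numbers 1 to 4, so that 2 of 4 pairs were lower in iCre, and the IL-1b differences were -0.16, -0.39, 0.14 and -0.45.

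Other lists also passed within a condition with the preset correlation, and none did with an estimated one (lowest adjusted p = 0.145). In SS 8 more did: oxidative phosphorylation (median 0.06, adjusted p = 0.0404), ERK feedback (0.13, 0.0227), NRF2 targets (0.23, 0.00232) and the mitochondrial genome (0.14, 0.0227) were higher in iCre, and matrix (-0.16, 0.0227), contractile (-0.21, 0.00114), cell cycle (-0.39, 0.000555) and fibroblast identity genes (-0.32, 0.00815) were lower. With bFGF they were oxidative phosphorylation (0.07, 0.0134), p53 targets (-0.09, 0.00935) and fibroblast identity (-0.21, 0.0284). With IL-1b they were the TCA cycle (0.06, 0.0203), oxidative phosphorylation (0.06, 0.000318), HIF targets (0.17, 0.0437) and matrix (-0.15, 0.0193), and with TGFb oxidative phosphorylation (-0.05, 0.0141), HIF targets (0.21, 0.0283), TGFb targets (-0.19, 0.0283) and matrix proteases (0.15, 0.0265). With the block the calls for oxidative phosphorylation and ERK feedback in SS (0.0535 each) and HIF targets with TGFb (0.0525) ended. Without number 4 only cell cycle (0.000424) and NRF2 targets (0.0259) of the 8 passed in SS, where the ERK feedback median turned to -0.17 (adjusted p = 0.24), and none of the 3 passed with bFGF (lowest adjusted p = 0.0939). The TCA call with IL-1b (0.0907) and that of TGFb targets with TGFb (0.158) ended there too.

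Adding bFGF asks what a fibroblast growth factor changes in these cells. With LacZ 429 genes changed (275 rose, 154 fell, 171 of them by at least 2-fold), and with iCre 368 (242 rose, 126 fell, 174 by at least 2-fold). Sele, the endothelial adhesion molecule E-selectin, rose 11.4-fold in LacZ (3.51 ± 0.63, adjusted p = 0.00459) and 11.7-fold in iCre (3.55). Spry4 rose 7.94-fold (2.99 ± 0.4, adjusted p = 0.000242) and 5.82-fold (2.54 ± 0.39, adjusted p = 0.00188), and Clec14a rose 7.4-fold and 5.48-fold. In LacZ the transcription factor genes Etv4 (5.87-fold) and E2f8 (5.44-fold) and the leptin receptor gene Lepr (5.85-fold) rose, and in iCre Esm1 (7.86-fold), Ifi27l2b (5.76-fold) and Selp (5.38-fold). Fgf18 fell to 0.183-fold in both. Sfrp2, a Wnt antagonist, fell to 0.0939-fold in LacZ, with Angpt4 (0.169-fold), Rasl12 (0.204-fold) and Xkr4 (0.217-fold). In iCre Clec3b (0.173-fold), Akr1c14 (0.204-fold), Xkr4 (0.214-fold) and Aff3 (0.262-fold) fell.

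Feedback genes of ERK signaling and cell cycle genes were higher with bFGF throughout. All 19 tested ERK feedback genes were higher with either vector (median 1.18 in LacZ, 1.09 in iCre). In LacZ 9 rose (13 adjusted over the list alone), among them Spred1 (1.18 ± 0.17, adjusted p = 0.000437), Spry2 (1.00 ± 0.17) and the ERK phosphatase gene Dusp6 (2.44 ± 0.44), and in iCre 5 rose (14 over the list alone). The list's adjusted p was 8.5e-22 in LacZ (adjusted p = 0.0234 with an estimated correlation, and 0.118 with the block as well) and 1.31e-17 in iCre (adjusted p = 0.0566 with an estimated correlation). All 31 cell cycle genes were higher (median 1.48 and 1.63). In LacZ 6 rose (26 over the list alone, 28 with the block), led by the replication helicase gene Mcm3 (2.64-fold, 1.4 ± 0.26, adjusted p = 0.00548), Mcm4, Mcm2 and Pcna, and in iCre 9 rose (28 over the list alone). That list's adjusted p was 4.65e-25 in LacZ (adjusted p = 0.193 with an estimated correlation) and 4.92e-32 in iCre (adjusted p = 0.0903 with an estimated correlation). Of 33 NFkB targets and cytokines 5 rose and 1 fell in LacZ, with Ccl7 (3.12-fold), Ccl2 (4.08-fold) and Vcam1 (2-fold) up and Cxcl5 down (0.253-fold), and 4 rose in iCre. The list's adjusted p was 0.0194 in LacZ (adjusted p = 0.303 with an estimated correlation, 0.051 with the block) and 0.00766 in iCre (adjusted p = 0.236 with an estimated correlation). In iCre the 13 mitochondrial genome genes were all lower (median -0.35, adjusted p = 0.00212, and adjusted p = 0.75 with an estimated correlation), and glycolysis genes were higher (17 of 21, 0.28, adjusted p = 0.0221, adjusted p = 0.75 with an estimated correlation, and 0.0539 with the block). No member of these last lists passed over all genes, and Slc2a1 stood at 0.43 ± 0.13 (adjusted p = 0.0781).

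Markers of vessel cells moved both ways with bFGF, and their lists did not pass. The mural marker Cspg4 rose in both vectors (2.6-fold and 2.73-fold, adjusted p = 0.0383 and 0.0325). In LacZ the endothelial marker Fabp4 rose (5.01-fold, adjusted p = 0.0444) and Tek fell (0.473-fold, adjusted p = 0.046), and in iCre they stood at 3.76-fold and 0.512-fold (adjusted p = 0.0976 and 0.0795). These calls ended in most fits with 1 library left out. Cspg4 missed the threshold without replicate 1, 2 or 3 of LacZ bFGF or replicate 1 or 2 of LacZ SS (1.15 to 1.4, adjusted p = 0.064 to 0.189), and without replicate 1, 2 or 3 of iCre bFGF or of iCre SS (1.24 to 1.56, adjusted p = 0.0595 to 0.15). Fabp4 missed it without replicate 1, 2 or 4 of LacZ bFGF or any LacZ SS library (1.78 to 2.54, adjusted p = 0.0554 to 0.155), and Tek without any LacZ bFGF library or replicate 1, 2 or 4 of LacZ SS (-1.14 to -0.92, adjusted p = 0.0688 to 0.21).

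The bFGF counts depend on which libraries are in the fit. With the block 2048 genes changed in LacZ and 1916 in iCre, and without number 4, 1638 and 2621. In LacZ the count was 142 without LacZ bFGF replicate 1, 108 without LacZ bFGF replicate 2, 95 without LacZ SS replicate 1, 73 without LacZ SS replicate 2, 936 without LacZ SS replicate 3 and 220 without LacZ SS replicate 4. In iCre it was 174 without iCre bFGF replicate 1, 48 without iCre bFGF replicate 2, 146 without iCre bFGF replicate 3, 1176 without iCre bFGF replicate 4, 49 without iCre SS replicate 1 and 40 without iCre SS replicate 2. Sele, Spry4, Fgf18 and Rasl12 in LacZ, and Sele, Spry4 and Fgf18 in iCre, passed in every such fit, as did Clec14a in LacZ. Without LacZ SS replicate 2, Etv4, E2f8, Lepr, Angpt4, Sfrp2 and Xkr4 all missed the threshold, and without iCre SS replicate 2 or iCre bFGF replicate 2 so did Esm1, Ifi27l2b, Clec14a, Selp, Clec3b, Akr1c14, Xkr4 and Aff3. Calls also ended without LacZ SS replicate 1 (Etv4, Lepr, E2f8, Sfrp2), LacZ SS replicate 4 (Etv4, Lepr, E2f8, Angpt4), LacZ bFGF replicate 1 (Etv4, E2f8, Sfrp2, Angpt4, Xkr4), replicate 2 (Etv4, Lepr, E2f8, Sfrp2, Angpt4), replicate 3 (Etv4, Angpt4) or replicate 4 (Etv4, Lepr, E2f8). In iCre they ended without iCre SS replicate 1 (Esm1, Ifi27l2b, Selp, Clec3b, Xkr4, Aff3), replicate 3 (Esm1) or replicate 4 (Esm1, Selp), and without iCre bFGF replicate 1 (Esm1, Clec3b), replicate 3 (Ifi27l2b, Clec3b) or replicate 4 (Clec3b). In LacZ the list members Mcm4, Mcm2, Pcna and Vcam1 missed the threshold without LacZ bFGF replicate 2 or LacZ SS replicate 1 or 2, and Mcm2, Pcna and Vcam1 without LacZ bFGF replicate 1 or LacZ SS replicate 4 as well (adjusted p = 0.0542 to 0.131). Ccl2 missed it without LacZ SS replicate 1 or 2 (adjusted p = 0.0648 and 0.0711). Over all libraries left out in turn, the highest adjusted p was 0.196 for Etv4, 0.157 for E2f8, 0.316 for Lepr, 0.456 for Angpt4, 0.354 for Esm1, 0.207 for Selp and 0.251 for Clec3b. Some sizes moved too, with Lepr at 1.08 without LacZ bFGF replicate 4, Angpt4 at -0.82 without LacZ SS replicate 4, Esm1 at 1.58 and Selp at 1.66 without iCre bFGF replicate 2, and Clec3b at -1.92 without iCre SS replicate 2. Without LacZ SS replicate 3 Sele was 4.25, Clec14a 3.55, Dusp6 3.03, Etv4 3.49 and E2f8 3.44. In the fits that lost their calls Etv4 stayed at 2.24 to 2.62 and E2f8 at 2.18 to 2.49.

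With IL-1b, the prototype inflammatory cytokine, 3216 genes changed in LacZ (1853 rose, 1363 fell, 1325 by at least 2-fold) and 2634 in iCre (1488 rose, 1146 fell, 1076 by at least 2-fold). Nos2 rose 585-fold in LacZ (9.19 ± 0.29, adjusted p = 1.51e-18) and 524-fold in iCre. The acute-phase gene Saa3 rose 567-fold and 433-fold, and Lcn2, an iron-sequestering protein, rose 343-fold and 322-fold. In LacZ Vnn3 rose 257-fold (8 ± 0.49), and in iCre Sprr2b rose 456-fold. The cytokine gene Csf3 had 3 counts over the 4 LacZ SS libraries, a ratio of 310 with a 95% counting interval of 106 to 1510, and rose 339-fold in iCre. Sprr2e also had 3 counts there (ratio 437, interval 149 to 2120), and with 0 counts in iCre SS it was at least 248-fold higher (against 3 counts over the group). Those intervals and bounds cover counting error alone. The fitted values in LacZ, which such low counts leave loose, went for Csf3 from 8.17 to 11.1 without LacZ SS replicate 4, and for Sprr2e from 8.55 to 6.9 without LacZ IL-1b replicate 3 and to 9.51 without LacZ SS replicate 3. Myh1 fell to 0.0128-fold (-6.29 ± 1.02, adjusted p = 6.88e-05) and 0.0249-fold, and Wscd2 to 0.045-fold and 0.059-fold. In LacZ the Notch target Hey2 (0.0316-fold), Daam2 (0.0488-fold) and Angptl7 (0.0268-fold) fell, and in iCre the related Heyl (0.0514-fold), Col8a2 (0.0599-fold) and Tnnt2 (0.0604-fold). Angptl7 missed the threshold without replicate 1, 2 or 3 of LacZ IL-1b or replicate 1 or 2 of LacZ SS (adjusted p = 0.0622 to 0.0856), and was -6.86 without LacZ IL-1b replicate 4. Lcn2 was 9.16 without LacZ SS replicate 4 and 8.92 without iCre SS replicate 4, Myh1 -6.97 without LacZ IL-1b replicate 2 and Tnnt2 -3.41 without iCre SS replicate 2.

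Of 33 NFkB targets and cytokines 30 rose with IL-1b in each vector and 0 fell. The list's median was 3.59 in LacZ, or 3.13 with Csf2, Csf3 and Cxcl3 at their counting bounds, and 3.43 in iCre. Sod2 rose 13.8-fold and 13.2-fold and Ccl7 58.1-fold and 40.4-fold, and the list passed with an estimated correlation (adjusted p = 7.87e-13 and 5e-13). Interferon-stimulated genes rose in 22 of 25 (LacZ, median 1.75) and 21 of 25 (iCre, 1.59), with Irf7 up 6.36-fold and 5.34-fold and Gbp2 7.2-fold and 6.58-fold. Their list had adjusted p = 7.54e-19 and 9e-17, but adjusted p = 0.0942 and 0.118 with an estimated correlation. Glycolysis genes rose in 15 of 21 with each vector (median 1.01 and 1.04), among them the lactate transporter gene Slc16a1 (4.04-fold and 3.92-fold), Slc2a1 (2.86-fold and 2.4-fold), the hexokinase gene Hk2 (5.74-fold and 4.07-fold) and Pfkfb3 (2.49-fold and 2.47-fold). This list had adjusted p = 3.82e-11 and 1.09e-12, and adjusted p = 0.0307 and 0.0264 with an estimated correlation (0.0877 and 0.0621 with the block as well).

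Pentose phosphate genes rose in 4 of 7 (LacZ) and 3 of 7 (iCre) with IL-1b, with Pgd up 2.58-fold and 2.08-fold and G6pdx, the entry enzyme, up 1.6-fold and 1.33-fold (list adjusted p = 6.98e-05 and 0.000572; adjusted p = 0.0266 and 0.0541 with an estimated correlation, and 0.0831 and 0.102 with number 4 left out as well). NRF2 targets rose in 9 of 12 in each vector, including the antioxidant genes Gsr (2.56-fold and 2.45-fold) and Srxn1 (4.08-fold and 2.64-fold), with adjusted p = 1.5e-09 and 4.53e-06 (adjusted p = 0.0307 and 0.111 with an estimated correlation, and 0.139 and 0.244 with number 4 left out as well). HIF targets rose in 7 and 6 of 14, with Vegfa up 2.52-fold and 2.13-fold (0.00471 and 0.000532; adjusted p = 0.246 and 0.183 with an estimated correlation). ATF4 and unfolded protein genes rose in 7 of 16 with 1 falling (LacZ) and in 6 of 16 (iCre), with the cystine transporter gene Slc7a11 up 12.5-fold (2.85 on the log2 scale without LacZ IL-1b replicate 3, and 4.24 without LacZ SS replicate 3) and 5.56-fold (0.00846 and 0.0122; adjusted p = 0.636 and 0.613 with an estimated correlation). Contractile genes fell in 8 of 18 (LacZ, median -1) and 3 of 18 (iCre, -0.7), with Vcl at 0.317-fold and 0.358-fold (8.54e-05 and 0.000532; adjusted p = 0.222 and 0.301 with an estimated correlation, and 0.0489 and 0.0355 with number 4 left out as well). Mural markers were lower in the same comparisons, with 3 of 8 falling in each vector (median -0.94 and -0.6), namely Mcam (0.18-fold and 0.197-fold), Notch3 (0.279-fold and 0.271-fold) and Cspg4 (0.345-fold and 0.395-fold). Their list missed the threshold (0.0521 and 0.13) and passed without number 4 (0.00661 and 0.0467, but adjusted p = 0.119 and 0.24 with an estimated correlation). Mcam missed the threshold without LacZ SS replicate 3 (-1.78, adjusted p = 0.0737) and without iCre IL-1b replicate 2 or 3 or iCre SS replicate 1 or 3 (-2.35 to -1.82, adjusted p = 0.0545 to 0.0812), and Notch3 without iCre SS replicate 1 or 3 (-1.62 to -1.57, adjusted p = 0.0502 to 0.0541).

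All 20 cholesterol synthesis genes were higher with IL-1b (median 0.72 and 1), and 1 rose in each vector, with 14 and 16 rising with the block. Their list missed the threshold in LacZ (0.0615; with the block 0.000149) and passed in iCre (0.011, but adjusted p = 0.685 with an estimated correlation and 0.0809 without number 4). It did not pass in LacZ with an estimated correlation in the unblocked fit either. Matrix proteases rose in 8 and 7 of 19, with Mmp3 up 9.11-fold and 8.23-fold, while the inhibitor gene Timp3 fell to 0.152-fold and 0.156-fold (list 0.0615 and 0.0975; with the block 0.0178 and 0.0269). In the unblocked fit this list did not pass with an estimated correlation in either vector. In iCre oxidative phosphorylation passed as a list with 0 of 24 members rising (0.0259, adjusted p = 0.613 with an estimated correlation, 0.0809 without number 4). There the mesothelial keratin gene Krt18 fell to 0.168-fold and Lrrn4 to 0.156-fold (list 0.0291, adjusted p = 0.107 with an estimated correlation, 0.0809 without number 4), and both missed the threshold without iCre IL-1b replicate 1 or 4 or iCre SS replicate 1, Krt18 also without iCre IL-1b replicate 2 or iCre SS replicate 4, and Lrrn4 also without iCre IL-1b replicate 3 or iCre SS replicate 2 (highest adjusted p = 0.115 and 0.175). Lrrn4 was -1.97 without iCre SS replicate 2 and -3.84 without iCre IL-1b replicate 2, and Krt18 -3.58 without iCre IL-1b replicate 3. In LacZ Lrrn4 fell by as much (0.156-fold, adjusted p = 0.025), and Krt8, with 0 counts over the LacZ IL-1b libraries, was at least 25.1-fold lower (against 3 counts over the group, adjusted p = 0.00929), while the list missed the threshold (0.0616). There Lrrn4 missed it without LacZ IL-1b replicate 1 or 3 or LacZ SS replicate 2 (-2.35 to -2.06, adjusted p = 0.0826 to 0.12) and was -3.48 without LacZ IL-1b replicate 2. The fitted value of Krt8 went from -7.24 to -6.5 without LacZ SS replicate 2, and without number 4 Krt8 did not pass (adjusted p = 0.0577). By the interaction test the mesothelial response did not differ between the vectors past the threshold (adjusted p = 0.98). With the block 5418 genes changed in LacZ and 4868 in iCre, and without number 4, 4874 and 4280. With total counts as the only scaling 1375 rose and 1625 fell in LacZ, and NRF2 targets rose in 5 of 12 in iCre.

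TGFb, the main inducer of the contractile myofibroblast state, changed the most genes. In LacZ 7759 changed (3925 rose, 3834 fell, 3076 by at least 2-fold) and in iCre 6417 (3378 rose, 3039 fell, 2288 by at least 2-fold). With the block 9787 genes changed in LacZ and 8651 in iCre. Acan, the cartilage proteoglycan aggrecan, rose 175-fold in LacZ (7.45 ± 1.16, adjusted p = 9.5e-06) and 315-fold in iCre. The hormone gene Fgf21 rose 131-fold and 71.5-fold, the chemokine gene Ccl17 75.5-fold and 84.3-fold, and the zinc transporter gene Slc39a2 61.2-fold and 82.4-fold. In LacZ Crabp2, a retinoic acid carrier, rose 65.6-fold and the cytokine gene Il11 38.7-fold (5.27 ± 0.63), and in iCre C1qtnf3 rose 403-fold (8.65 ± 2.1) and Cdh6 63.2-fold. The size for C1qtnf3 came from iCre TGFb replicate 4, with 1840 CPM against at most 43.1 CPM in any library of numbers 1 to 3, and without that library it was 3.87 (adjusted p = 0.0488). Number 4 was also high with LacZ, where C1qtnf3 stood at 791 CPM with TGFb and 4.74 CPM in SS. Galnt15 fell to 0.00583-fold and 0.0258-fold, the ferritin receptor gene Scara5 to 0.0168-fold and 0.0132-fold, and the matrix gene Tnxb to 0.027-fold and 0.0428-fold. Angpt2 fell to 0.0311-fold in LacZ, and Olfml2a (0.0335-fold), Sucnr1 (0.0352-fold) and Nptx1 (0.0464-fold) fell in iCre. Slc10a6 had 0 counts over the LacZ TGFb libraries and was at least 81.6-fold lower (3 counts over the group), and Gbp11 had 1 count there, a ratio of SS over TGFb of 157 (95% counting interval 27.8 to 6260). The fitted value of Slc10a6 went from -8.94 to -7.7 without LacZ SS replicate 4, and that of Gbp11 from -6.59 to -8.41 without LacZ TGFb replicate 1. The other values here that moved by over 1.5 times when 1 library was left out kept their calls. In LacZ Acan was 6.24 without TGFb replicate 4, Ccl17 7.18 without SS replicate 3, Galnt15 -8.28 and Scara5 -6.92 without TGFb replicate 2, and Angpt2 -6.31 without TGFb replicate 4. In iCre Acan was 7.25 without TGFb replicate 2 and 9.08 without SS replicate 1, Scara5 -5.15 without SS replicate 2, and Galnt15 -5.86 without TGFb replicate 4. Without iCre SS replicate 4 Slc39a2 was 7.03, C1qtnf3 9.61, Olfml2a -3.91 and Nptx1 -3.13, and without iCre TGFb replicate 4 Olfml2a was -5.55.

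Of the metabolic and synthetic lists, 6 passed with TGFb in each vector with the preset correlation, and none did with an estimated one. Cholesterol synthesis rose in 20 of 20 genes in LacZ (median 2.21) and in 19 of 20 in iCre (2.07), with Sc5d up 2.42-fold and 2.22-fold (list adjusted p = 3.99e-06 and 1.25e-06; adjusted p = 0.476 and 0.413 with an estimated correlation). Serine and one-carbon genes rose in 8 of 9 with each vector, among them Psph (5.49-fold and 4.83-fold) and Shmt2 (4.52-fold and 4.17-fold), while Shmt1 fell (0.312-fold and 0.465-fold; list 0.000994 and 0.000146; adjusted p = 0.254 and 0.216 with an estimated correlation). ATF4 and unfolded protein genes rose in 14 and 13 of 16, with the chaperone gene Hspa5 up 2.89-fold and 2.57-fold (8.09e-07 and 7.99e-07; adjusted p = 0.254 and 0.216 with an estimated correlation). Oxidative phosphorylation rose in 19 and 15 of 24, with Atp5g1 up 3.14-fold and 2.62-fold (2.97e-07 and 3.73e-06; adjusted p = 0.254 and 0.216 with an estimated correlation). Glycolysis rose in 10 and 11 of 21 with 1 falling in each, with Hk2 up 7.68-fold and 5.62-fold and Slc2a1 3.14-fold and 2.63-fold (0.00171 and 0.000301; adjusted p = 0.337 and 0.218 with an estimated correlation). Pentose phosphate rose in 7 and 5 of 7, with Pgls up 1.42-fold and 1.35-fold (0.00574 and 0.0245; adjusted p = 0.24 and 0.216 with an estimated correlation). TCA cycle genes went both ways, with 13 and 10 of 21 rising and 4 falling in each, among them Mdh2 (2.28-fold and 1.97-fold) and Pcx (0.456-fold and 0.518-fold), and the list did not pass (0.0622 and 0.0916).

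Contractile genes rose in 13 of 18 with each vector, with Tagln up 8.72-fold and 10.1-fold and the actin gene Acta2 7.17-fold and 10.3-fold (list 0.000936 and 3.73e-06; adjusted p = 0.337 and 0.216 with an estimated correlation). Of 20 TGFb targets 11 rose in each, with Pmepa1 up 5.78-fold and 5.12-fold, and 3 and 2 fell (0.000195 and 3.23e-05; adjusted p = 0.24 and 0.216 with an estimated correlation). Of 35 extracellular matrix genes 16 and 15 rose, among them the collagen cross-linking enzyme gene Lox (5.33-fold and 5.51-fold), while 4 and 2 fell, among them Col6a1 (0.339-fold and 0.387-fold; 0.0264 and 0.0015; adjusted p = 0.618 and 0.413 with an estimated correlation). Fibroblast identity genes fell in 12 and 11 of 16 (median -1.56 and -1.31), with Gsn at 0.214-fold and 0.261-fold, and Mfap5 rose 2.89-fold and 3.78-fold (0.00158 and 0.0015; adjusted p = 0.254 and 0.216 with an estimated correlation). Interferon-stimulated genes fell in 16 and 13 of 25 (median -1.08 and -0.79), with Ifit2 at 0.244-fold and 0.282-fold (0.000256 and 0.000645; adjusted p = 0.596 and 0.581 with an estimated correlation). Leukocyte markers were lower in the same libraries (median -0.74 and -0.53, 12 and 10 of 12 lower, 0 past the test in edgeR), and with the block 10 and 9 of them fell, with Adgre1 at -1.17 ± 0.18 and -0.72 ± 0.17.

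HIF targets (3 rose and 3 fell in LacZ, 2 and 3 in iCre) and p53 targets (6 and 5, 4 and 5) split with TGFb. Vegfa rose 3.95-fold and Adm fell to 0.179-fold in LacZ, and Plk2 rose 5.62-fold and Sesn1 fell to 0.301-fold. Matrix proteases fell in 7 and 5 of 19, with 3 and 2 rising (list 0.0622 and 0.0723; with the block 0.0162 and 0.0196). In the unblocked fit this list did not pass with an estimated correlation in either vector. Among markers of vessel cells, Tek fell (0.276-fold and 0.3-fold), Notch3 fell (0.155-fold and 0.186-fold), and Erg (16.7-fold and 22-fold, or 3.03 and 3.62 on the log2 scale without TGFb replicate 4 and 5.27 and 5.13 without SS replicate 4 of the same vector) and Cspg4 (6.12-fold and 5.62-fold) rose. With total counts as the only scaling the median of all genes shifted by -0.2 in LacZ and -0.22 in iCre, so that 2553 rose and 5078 fell in LacZ and 1918 and 4630 in iCre. Under that scaling 3 TCA genes rose and 5 fell in iCre, oxidative phosphorylation rose in 10 and 7 of 24, and the medians of HIF (0.05 to -0.16) and p53 targets (0.11 to -0.09) in LacZ changed sign.

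**Figure D2:**
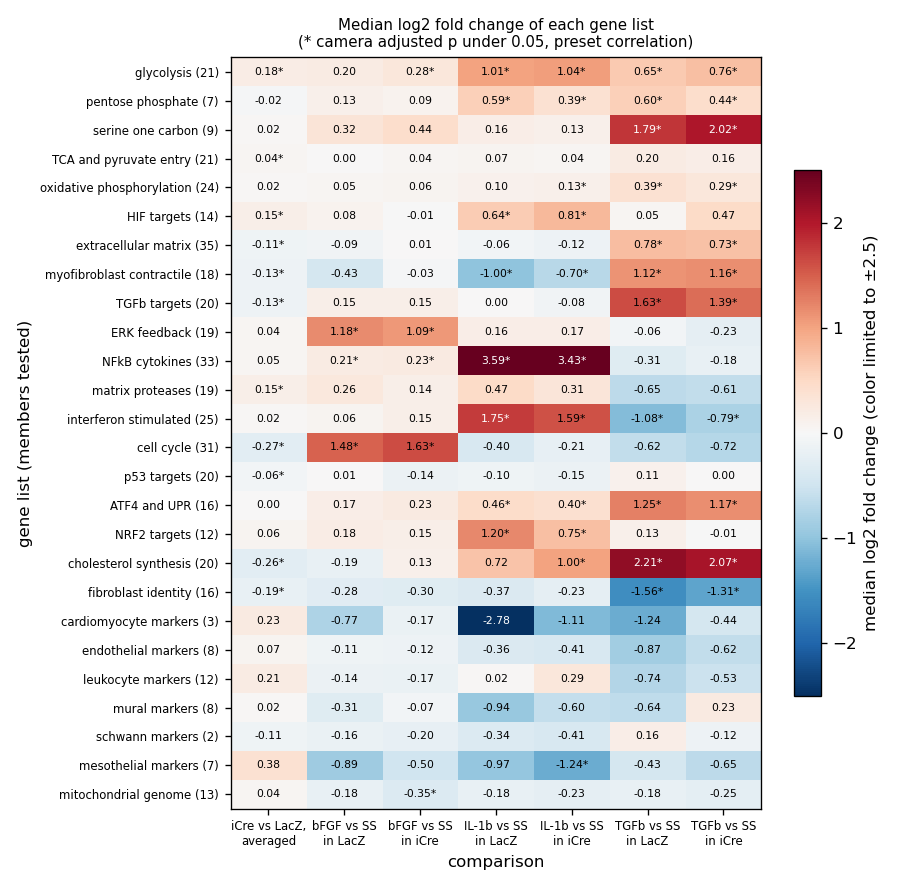
Median log2 fold change of 26 gene lists (rows, tested members in parentheses) in 7 comparisons (columns), with color limited to 2.5 in either direction and an asterisk where the camera adjusted p was under 0.05 with the preset correlation. NFkB targets are highest with IL-1b and cholesterol synthesis with TGFb in both vectors, and medians of up to 0.23 (TCA cycle, HIF, p53 and NRF2 targets, Schwann, mural and leukocyte markers, TGFb targets, pentose phosphate, ATF4 and matrix) changed sign with total-count scaling in at least 1 column.

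Whether iCre alters the response to a stimulus was tested by interaction. In edgeR 0 genes passed for bFGF, IL-1b or TGFb, with 67, 93 and 201 at an unadjusted p under 0.05, and DESeq2 also gave 0 (75, 100 and 224 unadjusted). These unadjusted counts lie below a share of 0.05 of the 16760 genes tested, in fits that leave out the pairing. The pair block gave 0 too, with 190, 330 and 763 unadjusted. Pkm had interaction values of 0.10, 0.04 and 0.09 (each ± 0.32, adjusted p = 1). The responses of the vectors shared many genes and none moved in opposite directions. With bFGF 151 genes rose in both and 79 fell in both (4 and 1 if calls were independent), with IL-1b 1325 and 875 (165 and 93), and with TGFb 3165 and 2728 (791 and 695). These overlaps compare each vector with its own SS libraries, so they share the replicate numbers. Among the lists, NRF2 targets had the lowest interaction p, for IL-1b (median -0.33, adjusted p = 5.58e-05, and adjusted p = 0.662 with an estimated correlation).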

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

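Of the tests in this part, 3 that thin the deeper libraries were fixed before their results were seen. The list tests on all libraries, the interactions and the fits with the replicate block had been planned as well. Every other test here, including all splits of the libraries, was chosen afterwards.

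Libraries of replicate number 4 stood apart from numbers 1 to 3. In a model with the numbers as terms 9526 genes differed in number 4, with 433 at least 4-fold higher and 333 at least 4-fold lower. Loss of a minor cell type cannot raise other genes that far, so a lower share of leukocytes, whose markers had a median log2 level of -2.47 in number 4, is argued against as the whole cause by the 433 higher genes. After thinning all libraries to the lowest total 91.3% of the genes at least 4-fold apart remained so. Totals ran only from 20736203 to 34995038 and the values were scaled. Thinning could therefore hardly undo a 4-fold difference and decides little about library size. A separate animal, isolation or dissection may lie behind number 4, but the labels give none and these were not tested.

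Pkm was lower in iCre than in LacZ in 16 of 16 pairs. After each iCre library was thinned to its LacZ partner the averaged value was -0.51 ± 0.11. Pkm had at least 10241 counts in every library, so thinning could hardly move its scaled value and decides little about depth. Loss of the reads of the deleted exon alone stays open. The exons that set PKM1 and PKM2 apart are 167 bp each and at most 8.18% of a transcript, which with reads spread evenly would take the count to -0.12 on the log2 scale, but coverage along the transcript was not measured, so the larger decrease does not exclude it. Activity of Cre apart from Pkm stays open, because 0 groups had iCre in cells without the floxed allele. A lower level of the recombined transcript is another candidate explanation, which the gene counts cannot test.

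Cholesterol synthesis genes were lower in iCre, with 20 of 20 lower on average over the conditions. After thinning the median was -0.26 as before. With a mean depth ratio of 1.17, thinning of scaled counts had little room to move it and decides little about depth. All 4 numbers had a mean list difference below -0.1 (-0.44 to -0.25), which argues against a single number as the source. The list did not pass with an estimated correlation (adjusted p = 0.636). Cre activity apart from Pkm could also be the source, and 0 groups decide it. An effect of recombination at Pkm, which was not measured, and one of Cre itself therefore cannot be told apart here.

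Other splits of the same libraries were used to ask whether the counts of changed genes could arise by chance. Over all 35 splits the real one gave the most genes for IL-1b and TGFb. That set ignores the pairing by number, so its shares cannot exclude chance. In LacZ the real split gave 3383 genes for IL-1b (highest other 1) and 6876 for TGFb (highest other 0), and in iCre 1979 (highest other 328) and 4752 (highest other 0), each as the only 1 of 35 splits. Nor can chance be excluded for bFGF over the same 35. There the real split gave 19 genes in LacZ, as many in 2 of 35 (highest other 2546). In iCre it gave 18, as many in 3 of 35 (highest other 969). The other splits with as many put both libraries of number 3 on the same side and do not part all pairs, which points to the replicate numbers as a structure of the samples, and with the block bFGF gave 2048 and 1916 genes. For iCre against LacZ within a condition the real count was 0, so that 35 of 35 splits had to give as many and the test says nothing, and the highest others were 2311 in SS, 306 with bFGF, 939 with IL-1b and 527 with TGFb. In each of these the highest other set numbers 1 and 3 against 2 and 4, which points to the same structure. Of the 8 splits that part all 4 pairs, those other than the real one gave at most 0 genes for each stimulus, for iCre within each condition and for each interaction, and at most 1 for the average. Those 8 are too few for a share under 0.05, so within the pairing no share is given. Over the 50 splits drawn, which also ignore the pairing, chance cannot be excluded for the average (18 genes, as many in 6 of 50 splits, highest other 5303). For the interactions the real count of 0 again fixes the outcome (50 of 50, highest other 3 for bFGF, 3 for IL-1b and 1158 for TGFb). With the replicate block the average gave 475 genes.

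Some single libraries lay far from the other 3 of their group. The mitochondrial share was 0.655% in LacZ TGFb replicate 3, against 0.512 to 0.53%. The mean log2 CPM of 3 cardiomyocyte markers was 1.309 in iCre TGFb replicate 4, against -0.05163 to 0.1635. That of 2 Schwann markers was 1 in LacZ TGFb replicate 4 (others 2.271 to 2.373), 1.036 in iCre SS replicate 4 (1.932 to 2.056) and 0.4504 in iCre IL-1b replicate 4 (1.686 to 1.712). In all 96 such tests were run (12 measures in 8 groups), of which chance gives about 4.8, and 4 of the 5 found were number 4.

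Some gene lists differed between the vectors in their response by the interaction test with the preset correlation, and none did with an estimated one. For bFGF these were contractile genes (median 0.20, adjusted p = 0.0286), cholesterol synthesis (0.33, adjusted p = 0.0286) and the mitochondrial genome (-0.16, adjusted p = 0.0173), each with adjusted p = 0.958 with an estimated correlation. For IL-1b they were interferon-stimulated genes (-0.14, adjusted p = 0.0121; 0.987 with an estimated correlation) and NRF2 targets (-0.33, adjusted p = 5.58e-05; 0.662 with an estimated correlation). For TGFb they were pentose phosphate (-0.17, adjusted p = 0.0278; 0.834 with an estimated correlation), oxidative phosphorylation (-0.11, adjusted p = 0.000133), ERK feedback (-0.18, adjusted p = 0.0275) and interferon-stimulated genes (0.38, adjusted p = 0.0275), the last 3 with adjusted p = 0.87 with an estimated correlation. Without number 4 the calls for contractile genes (0.567), cholesterol synthesis (0.329), ERK feedback (0.408) and the TGFb interferon list (0.524) ended, and the contractile call also ended with the block (0.0619). With the block and the preset correlation 2 lists passed for bFGF, 3 for IL-1b and 9 for TGFb. Of those, 2, 2 and 4 were calls named above.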

How the results depend on the processing

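All fits with the pair block, without number 4 or with summed counts were added after the data were seen. Of 414 named-gene results past the threshold, 0 reversed under the alternatives run for single genes (the grouping by tags was run for counts alone). All stayed past it with DESeq2's size factors and with the block, 17 missed it with total counts, 38 with no filter, 72 of 403 in fits to the contrast's libraries alone and 10 without number 4, and 6 of 7 with summed counts. With 1 library left out 353 of 3480 fits missed it. Each cause was not tested, except that fits to fewer libraries have fewer degrees of freedom. Counts for IL-1b and TGFb stayed within 1.5 times under both other scalings, both filters and DESeq2. Leaving out 1 library gave 2260 to 3154 genes (IL-1b, LacZ), 1832 to 2612 (IL-1b, iCre), 6868 to 7581 (TGFb, LacZ) and 5274 to 7016 (TGFb, iCre), against 7 (without iCre SS replicate 1) to 25 (without iCre TGFb replicate 2) for the averaged 18, 73 to 936 for bFGF in LacZ and 40 to 1176 for bFGF in iCre.

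The averaged count of iCre against LacZ was 85 in DESeq2, 475 with the block, 982 with the pair block, 114 without number 4, 547 without it and with the block, and 9 with summed counts. Within conditions the block gave 1 (bFGF) and 5 (TGFb), the pair block 14 (SS), 15 (bFGF) and 46 (TGFb), and the block without number 4 gave 13 (bFGF), against 0. For bFGF in LacZ and iCre the counts were 881 and 856 in DESeq2, 212 and 190 with no filter, 19 and 18 in the contrast's libraries alone, 2048 and 1916 with the block, 1638 and 2621 without number 4, and 2945 and 4192 with both. For IL-1b they were 5418 and 4868 with the block, 4874 and 4280 without number 4, and 5970 and 5479 with both. Grouping LacZ libraries by their tags gave 2474 (iCre, SS), 879 (iCre, bFGF), 6156 (iCre, IL-1b), 3063 (bFGF, LacZ) and 6341 (IL-1b, LacZ), since it compares different treatments.

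Pkm averaged passed in DESeq2 (-0.50, adjusted p = 0.00625), with the block (-0.51, 0.00381), with the pair block (-0.51, 3.69e-06), without number 4 (-0.50, 0.027) and with both (-0.50, 0.00318), and missed the threshold with summed counts (-0.49, 0.0572), both other scalings (-0.50, 0.0717; -0.47, 0.0585) and both filters (-0.49, 0.0892; -0.50, 0.0674). It ran from -0.56 (without iCre SS replicate 3) to -0.44 (without LacZ SS replicate 3) with 1 library left out. Of 350 list tests 96 passed with the preset correlation and 7 with an estimated one. The interferon list's TGFb interaction changed direction without number 4 (adjusted p = 0.524), and the cause was not tested. Depth was tested by thinning for Pkm, the cholesterol list, the number 4 genes and the averaged count alone (18 genes before and after, and 475 and 464 with the block).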

Other observations

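The tests in this part were all chosen after the values were seen, and the genes were picked from them.

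Single genes set the replicate numbers apart. In the 8 libraries of number 4 the imprinted RNA H19 stood at 1080 ± 1310 CPM (SD, n = 8), against means of 7.04 to 13.4 CPM in the other numbers, and each of the 8 lay above every library of the other numbers. There the limb and lung patterning gene Tbx4 stood at 58.2 ± 23.8 CPM (0.924 to 1.76 in the others), the homeobox gene Hoxa5 at 18.1 ± 5.13 (0.331 to 3.87), the Wnt agonist gene Rspo3 at 59.1 ± 39.1 (0.453 to 1.41) and Agtr2 at 104 ± 78.3 (0.198 to 1.16). H19 in number 4 was 993 CPM in LacZ SS and 1060 with bFGF, against 63.4 with IL-1b and 101 with TGFb, and 2470, 3610, 128 and 183 in the matching iCre libraries. With 1 library per value these differences were not tested.

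Number 2 stood out for the pericyte marker Rgs5, at 291 ± 233 CPM (SD, n = 8) against 15.8 to 76.2 in the other numbers, although the median of the 8 mural markers there was 0.13. Number 3 had the most of the macrophage marker Adgre1, at 26 ± 6.93 CPM, with each of its 8 libraries above the others of the same group. Number 4 had the least, at 1.97 ± 0.617. Genes that differed from the other numbers numbered 2853 for number 1, 1090 for number 2, 5737 for number 3 and 9526 for number 4 in the model with the numbers as terms. Those at least 4-fold higher numbered 6, 19, 176 and 433.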
